A study of Mus musculus with 4 samples.

How the data were processed

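Total RNA of 4 mouse ES cell cultures was extracted with Trizol, labelled with biotin from 8 microgram per sample and hybridised to 1 Affymetrix array each, per the labels' protocols. The deposited values are signal intensities per probe set on a linear scale, computed with MAS5 per the submitters' processing notes. The MAS5 version, its scaling target, its background settings and detection calls are not given in the sources used here. The trimmed mean signal, leaving out 2% at each end, was 4.89 in homozygous replicate 1 (ko1), 4.33 in replicate 2 (ko2), 7.12 in wild type and 4.43 in heterozygous, so no common scaling target was visible. The 18 probe sets of spiked bacterial transcripts had median signals of 641.5, 844, 699.3 and 483.2 in the same order. All 4 columns were mapped to samples by the labels.

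Gene names came from the platform's annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none, 51 of them controls; 34754 were matched by gene ID to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. Probe sets with several or no symbols were left out of gene counts. No genome build is tied to the array table, so chromosomes are those of that gene table and no coordinates are given. Each of the 18194 genes was represented by its probe set with the highest mean signal, and 13729 genes with a mean signal above 2.55, the 40th percentile over all probe sets, were tested.

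Signals were analysed as log2(signal + 0.675), where 0.675 is the 20th percentile of all deposited values. Fold changes are on that scale, which understates changes of dim genes. The authors' between-array scaling was kept. The main fit was limma 3.58.1 in R 4.3.3 with 1 mean per genotype (lmFit, contrasts, eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. That design has 1 residual degree of freedom, the difference between the 2 homozygous lines; the lone wild type and heterozygous arrays were assumed to vary likewise. With the information limma borrowed across genes the total was 47.83 degrees of freedom, which fell to 9.262 after quantile normalization and 6.45 without the intensity trend. A second fit set both homozygous arrays against wild type and heterozygous together, with 2 residual degrees of freedom; there limma took the variance of each gene wholly from the trend, so that its p-values rest on the trend. Nothing in the labels says that arrays came from repeated cultures, so the p-values measure only the spread between these samples. No depth applies to arrays.

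The differences relative to the median gene are log2 differences minus their median over the tested genes. Background on each array was the brightest of 27 control probe sets of bacterial transcripts that are not spiked: 5.55 in ko1, 3.82 in ko2, 7.57 in wild type and 6.92 in heterozygous. By that measure 45.8%, 34%, 41.4% and 59.9% of the tested genes were at or below background. Where the probe set used for a gene was at background on every array of the dimmer side, the fold is given as at least the mean of the brighter side over that background, relative to the median gene. That bound leaves out the pseudocount, and the fitted fold is given where it is smaller. Where only 1 homozygous line was at background in a fall, that line was set at its background on the scale of the fit.

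Fixed lists of genes (20) were tested with limma's camera with a preset correlation of 0.01, adjusted over the 19 lists with 5 or more members measured. Measured here means past the signal filter. The test was repeated with an estimated correlation, which rests on the 1 residual degree of freedom and so could hardly call any list. The median of each list was also placed among 10000 random lists of like expression. Chromosomes were tested the same way. The position of the heterozygous array was compared with 100 simulations of unchanged groups. The tests, lists, alternatives and the rule for named genes were set before the data were examined. The rule took, for homozygous against wild type, the 12 largest rises and 12 largest falls among called genes with both homozygous arrays on the same side of the wild type and heterozygous arrays; for homozygous against heterozygous, 4 of each by the same rule; for heterozygous against wild type, the 6 largest differences each way as values. From each list it took up to 4 members with the largest difference and all called members where these were 6 or fewer, and any member of the pluripotency, cell cycle and SWI/SNF lists. It also took all probe sets of Arid1a and Arid1b. Endoderm and other called members beyond these numbers, and endoderm members that did not pass, were named to complete a list's count. The fibrillar collagen genes of the fibroblast list were named outside the rule. Predicted genes were counted, not named (1 among the called).

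The alternatives were a pseudocount divided by 16 or at the 40th percentile, quantile normalization, median centring, no filter or one at the 60th percentile, probe sets averaged per gene or each tested alone, no intensity trend, fits of fewer arrays, and leaving out each array. Centring on the tested genes and the list test in the fit of 2 groups were added after seeing the data. The fits were tested on 10 simulated data sets of 13729 genes with 200 changed genes, all above the median expression, and with noise drawn independently for each gene. For homozygous against wild type with the signals as deposited, 95.4% of genes raised by 4 on the log2 scale and 48.8% of those lowered by 4 were recovered, and 14.6% and 17.8% at a change of 2. In these data sets, which kept the unequal array levels, 34.7 unchanged genes were called lower and 2.3 called higher on average. After quantile normalization these were 5.8 and 5.6. The 200 changed genes were present too, so these counts do not give the effect of array levels alone. For the list test of that comparison, a list of 20 genes raised by 1.5 was called in 10 of 10 data sets, and unchanged data gave 0.1 called lists on average. With independent noise, these list results cannot show how the test behaves when genes are correlated.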

Results

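Gene expression was measured in mouse embryonic stem (ES) cells that differed in their copies of BAF250, the subunit with an ARID DNA-binding domain that defines the BAF form of the SWI/SNF chromatin remodelling complex. Total RNA of 4 cultures was hybridised to Affymetrix oligonucleotide arrays of 45101 probe sets, 1 array per culture. The labels name 2 homozygous knock-out lines, ko1 and ko2 (replicates 1 and 2 of the homozygous group), 1 heterozygous line and 1 wild type line. The cells were grown without feeder cells, on gelatin, in serum with leukaemia inhibitory factor, per the labels. The number of arrays limits the precision of every comparison: only the homozygous group had more than 1 array, so the spread between the homozygous lines stood in for that of the single wild type and heterozygous cultures. The arrays differed in signal level: the median signal was 2.70 in ko1, 2.61 in ko2 and 2.74 in the heterozygous array, and 4.01 in wild type. The median log2 difference over the 13729 genes tested was -0.75 for homozygous minus wild type, -0.03 for homozygous minus heterozygous and -0.68 for heterozygous minus wild type. Log2 differences and folds are therefore given relative to the median gene of the same comparison, while adjusted p-values come from the signals as deposited. The actin control probe sets at the 3' end were 5.01 times as bright as those at the 5' end in ko1, against 2.61 in ko2, 2.86 in heterozygous and 1.3 in wild type, so this sign of RNA quality differed between arrays, with ko1 furthest from wild type.

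The first question was what the arrays showed of BAF250 itself, a name shared by the mouse genes Arid1a (BAF250a) and Arid1b (BAF250b), since the labels give no letter. In the signals as deposited, Arid1a was lower in both homozygous lines than in wild type, and the heterozygous array lay between. Its brighter probe set had signals of 7.03 in ko1 and 3.57 in ko2 against 109 in wild type and 50.4 in heterozygous. The ko2 value lay below that array's background of 3.82; with it set at background the homozygous lines were at least 11.1-fold lower than wild type (fitted log2 difference -3.52 ± 0.61 (SE), limma adjusted p = 7.39e-06). Against heterozygous they were at least 8.5-fold lower (adjusted p = 0.00145), and heterozygous minus wild type was -0.42 ± 0.70 (adjusted p = 0.672). The second Arid1a probe set read 17.3 and 1.06 in the homozygous lines, 42.9 in wild type and 24.1 in heterozygous. Relative to the median gene it stood at -2.22 for homozygous minus wild type, with the lines far apart. Heterozygous minus wild type was -0.13 on it, so the middle position of heterozygous was mostly the level of that array. The only Arid1b probe set read between 0.233 and 6.14, below the background of its array in all 4 arrays, and was not tested. Which part of the gene was altered is not given in the sources used here, so a probe set that lies outside it would check nothing.

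The comparison of homozygous with wild type cells asked which transcripts differ when both copies are disrupted. Among the strongest rises were genes of extraembryonic endoderm and of the basement membrane that this tissue lays down. Col4a2 and Col4a1, the 2 chains of the main type IV collagen, had signals of 763 and 379 (Col4a2) and 1120 and 663 (Col4a1) in the homozygous lines. Wild type read 1.15, below background, for Col4a2 and 10.3 for Col4a1. Col4a1 rose 132-fold (7.04 ± 0.56, adjusted p = 3.73e-11) and Col4a2 at least 119-fold (adjusted p = 1.71e-15). The laminin chain genes rose with them: Lama1 62.0-fold (5.95 ± 0.56), Lamb1 at least 27.7-fold on its brightest probe set (log2 difference 3.57 on another, with wild type above background at 10.3) and Lamc1 12.5-fold (3.64 ± 0.55). Sparc, a secreted matrix protein abundant in parietal endoderm, rose 54.9-fold (5.78 ± 0.83), from a signal of 90.7 to 3880 and 2310.

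Of 24 members measured of the endoderm list, 11 rose, 0 fell and 13 did not pass the test; adjusted over the list alone, 16 rose and 1 fell. The list's median log2 difference was 3.54, 3.88 in ko1 and 3.15 in ko2, and the list as a whole was higher than the other genes (camera adjusted p = 1.68e-22 with the preset correlation). With an estimated correlation the call was lost (adjusted p = 0.563 with an estimated correlation), as it was for each of the lists called here. That setting rests on the 1 residual degree of freedom, so these losses cannot show that correlation between genes made the calls. For the endoderm list itself the estimated correlation was 0.681, far above the preset 0.01. Its p-value with the preset may therefore be too small, though that estimate rests on the same 1 degree of freedom. For the pluripotency list the estimated correlation, -0.0345, lay below the preset 0.01, yet its camera p went from 8.21e-07 to 0.113. The other risen members were Srgn, a granule proteoglycan (at least 20.2-fold), Fst, the activin antagonist follistatin (at least 14.9-fold; its other probe set read 12.7 and 18 against 6.08 in wild type, below background), Cubn, an endocytic receptor of visceral endoderm (at least 10.9-fold), and the transcription factors Sox17 (at least 8.87-fold, adjusted p = 0.0407) and Gata4 (10.0-fold, adjusted p = 0.0184); the calls of Sox17 and Gata4 ended after quantile normalization, and that of Gata4 also when probe sets were averaged (2.79, adjusted p = 0.163). Gata6, another endoderm regulator, read 25.5 and 23.4 against 3.20 in wild type without passing the test (adjusted p = 0.0726). Foxa2 and Dab2 did not pass either, although Dab2 read 65.6 and 30.6 against 10.4 in wild type (log2 difference 2.79). Apoe, Hhex and Hnf4a, which also mark endoderm, had log2 differences of -0.58, -0.31 and 0.08. In 18 of the 24 genes both homozygous lines lay above both other arrays, against 11% of all tested genes. The actin ratio given above was higher in ko1 and ko2 than in wild type, the same arrays in which these genes were higher, and was at 2.86 in the heterozygous array, in which they were not.

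**Figure D1:**
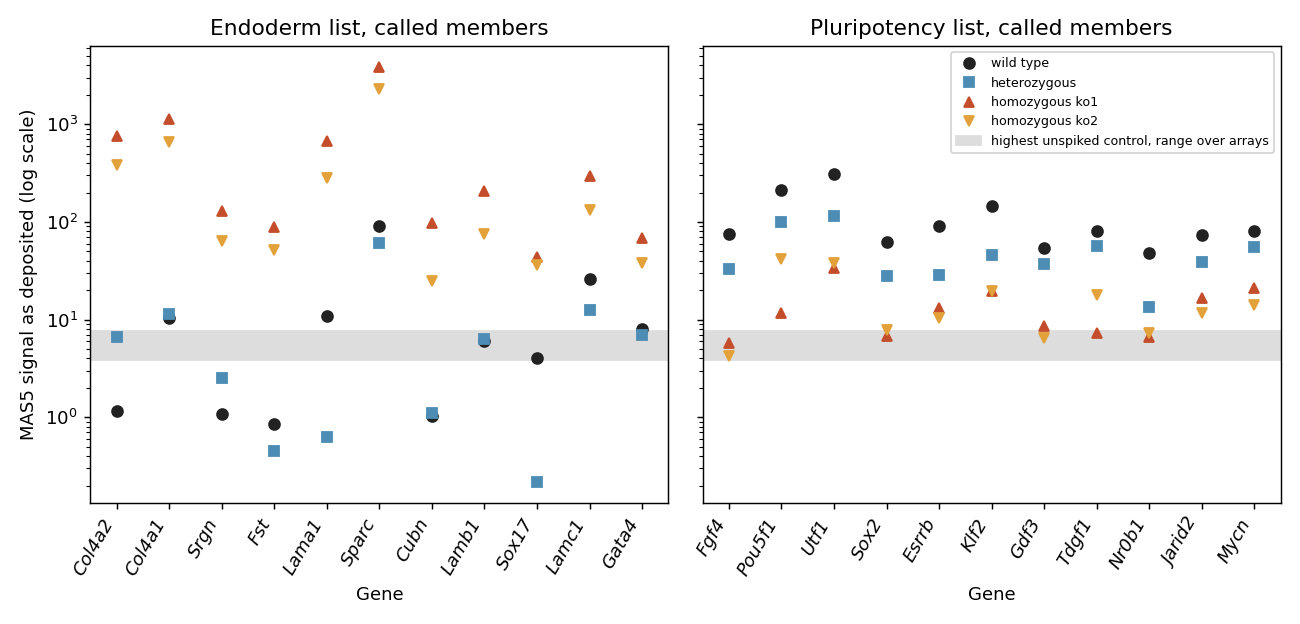
MAS5 signal of each of the 4 arrays (log axis) for the 11 endoderm genes that rose (left) and the 11 pluripotency genes that fell (right) in homozygous against wild type cells; each point is 1 array, and the grey band spans the background of the 4 arrays, 3.82 to 7.57. Both homozygous lines lie above wild type and heterozygous for the endoderm genes and below them for the pluripotency genes, from a Sparc signal of 3880 in ko1 down to an Fgf4 signal of 4.27 in ko2.

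Outside that list, the named rises included Pth1r, the parathyroid hormone receptor, a marker of parietal endoderm (at least 19.6-fold), Cited1, a transcriptional coactivator (at least 16.7-fold), and Clu, the secreted chaperone clusterin (44.7-fold, 5.48 ± 0.54). Hs3st1, a heparan sulphate sulphotransferase, and Tgoln1, a protein of the trans-Golgi network, rose at least 8.52-fold and at least 8.38-fold on the probe sets used. For Tgoln1 another probe set, above background in wild type, stood at 0.51, and its call ended when probe sets were averaged (1.95 ± 0.80, adjusted p = 0.457). Tgoln1 read 8.17 in heterozygous, above that array's background, on the probe set used. Of the hypoxia and glycolysis list (22 measured, median 0.50, adjusted p = 0.23), only P4ha1 and P4ha2 rose. P4ha1 rose 40.6-fold on the scale of the fit (on the brighter probe set), with wild type at 7.54, just below background, and P4ha2 at least 6.96-fold. Both encode prolyl hydroxylases that modify collagen chains, and the call of P4ha2 ended after quantile normalization. The other P4ha1 probe set read 36.7 and 39.4 against 16.9 in wild type, a log2 difference of 1.89. The simple epithelial keratin genes Krt18 (9.78-fold, 3.29 ± 0.56) and Krt8 (7.06-fold, 2.82 ± 0.55, adjusted p = 0.0489) rose too; both stand in the trophoblast list and in the actin cytoskeleton and adhesion list.

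Genes that maintain pluripotency were lower in the homozygous lines. Pou5f1, which encodes the core factor OCT4, fell from a signal of 213 to 11.7 and 42.1, 5.53-fold (-2.47 ± 0.58, adjusted p = 0.000576), with 98.7 in heterozygous. Sox2 fell 4.73-fold (-2.24 ± 0.62), Esrrb 4.49-fold (-2.17 ± 0.57) and Klf2 4.31-fold (-2.11 ± 0.54). Fgf4, the growth factor gene driven by OCT4 and SOX2, fell 8.10-fold (-3.02 ± 0.63), and Utf1 5.08-fold (-2.34 ± 0.54). Of 29 members measured, 11 fell, 0 rose and 18 did not pass; adjusted over the list alone, 19 fell and 0 rose. Gdf3, Tdgf1, Nr0b1, Jarid2 and Mycn complete the 11. After quantile normalization 0 of these 11 calls held, while the list as a whole kept its call. Relative to the median gene the differences hardly moved (Fgf4 to -2.97 ± 0.52, Sox2 to -2.16 ± 0.51, Utf1 to -2.21 ± 0.40), but the tests take the whole difference, in which the median gene moved from -0.75 to -0.18. The total degrees of freedom also fell, from 47.83 to 9.262. With probe sets averaged, the calls of Esrrb (-1.19 ± 0.65, adjusted p = 0.128; another of its probe sets stood at 0.19) and Mycn (-1.50 ± 0.71, adjusted p = 0.0885) ended. Nanog read 7.56 and 7.88 against 45.1 in wild type and 11.7 in heterozygous (-1.70 ± 0.67) and did not pass (adjusted p = 0.0562). Members above the median gene, none past the test, were Klf4 (1.19 ± 0.58), Dppa3 (0.62 ± 0.66), Tbx3 (0.43 ± 0.84), Tfcp2l1 (0.18 ± 0.69) and Sall4 (0.05 ± 0.55). The list's median was -1.25, -1.65 in ko1 and -1.14 in ko2, and the list was lower than other genes (camera adjusted p = 7.8e-06, but adjusted p = 0.563 with an estimated correlation). In 20 of the 29 genes both homozygous lines lay below both other arrays, against 26.9% of all tested genes. The actin ratios of these homozygous arrays were 5.01 and 2.61; that of heterozygous was 2.86, while the list stood at -0.22 in heterozygous against wild type.

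The primed epiblast list was lower as a list (median -1.08 over 17 genes, camera adjusted p = 0.00751, but adjusted p = 0.563 with an estimated correlation), although none of its members passed alone. Otx2 read 0.756 and 2.49 against 23.3 in wild type, Foxd3 1.54 and 0.730 against 15.6, and Sox3 1.91 and 1.52 against 15.3. A second Sox3 probe set went the other way, with 7.24 and 7.90 against 0.452. Trh, which encodes the precursor of thyrotropin-releasing hormone, fell at least 11.4-fold, to background in both homozygous lines (adjusted p = 4.84e-06). Slc7a3, a cationic amino acid transporter, fell at least 7.90-fold, and Phc1, a subunit of polycomb complex 1, fell 5.64-fold (-2.50 ± 0.54). Further falls by the same rule were in Tet1, a 5-methylcytosine oxidase (at least 4.32-fold), Bcam, a laminin-binding adhesion molecule (at least 4.50-fold), Parp1 (at least 4.71-fold), Ccnd1, the gene of cyclin D1 (at least 2.96-fold), Tigd5 (at least 3.33-fold), Tmem40 (at least 6.11-fold) and Myrf (at least 4.70-fold). Of these, Tet1, Bcam, Parp1, Ccnd1 and Tigd5 were below background in ko1 alone. Parp1 and Ccnd1 differed widely between the lines, with signals of 2.41 and 41.3 for Parp1 and 0.796 and 11.6 for Ccnd1. The falls of Tigd5 and Tmem40 rest on the probe set used. Another Tmem40 probe set, above background in both homozygous lines and wild type, stood at -0.25. The calls of Tigd5 and Tmem40 ended when probe sets were averaged (-0.46, adjusted p = 0.46, and -0.45, adjusted p = 0.495).

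In the list of cell cycle drivers (29 measured, median -0.29, camera adjusted p = 0.189), Ccnd2 rose 8.72-fold (3.12 ± 0.54, adjusted p = 0.013), while Ccnd1, Mcm2 (-1.49 ± 0.55) and Pcna (-1.38 ± 0.56) fell. The calls of all of these ended with a sixteenth (1/16) of the pseudocount (Ccnd2 3.25, adjusted p = 0.0522), those of Ccnd1, Mcm2 and Pcna also after median centring, and that of Mcm2 also when probe sets were averaged (-1.05, adjusted p = 0.0551). The cyclin genes thus went opposite ways: Ccnd2 read 132 and 107 against 22.3 in wild type. Among 24 SWI/SNF subunits Arid1a fell and 23 did not pass; the list lay lower (median -0.65, camera adjusted p = 0.0273, but adjusted p = 0.563 with an estimated correlation). That call, like the one of the primed epiblast list, also ended when probe sets were averaged per gene; the SWI/SNF call ended in the fit of 2 groups too. The catalytic subunit gene Smarca4 stood at -0.91 ± 0.54. In the polycomb and DNA methylation list (20 measured, median -0.49, adjusted p = 0.0201, but adjusted p = 0.563 with an estimated correlation), Tet1, Cbx7 (at least 3.57-fold) and Jarid2 (-1.59 ± 0.56) fell and none rose. The heat shock and oxidative stress list was lower (median -0.47, adjusted p = 0.0481, but adjusted p = 0.563 with an estimated correlation) with 2 of 20 members falling, Gclm and Sod2, both antioxidant genes. The call of the list also ended after quantile normalization, after either centring, with a sixteenth (1/16) of the pseudocount and in the fit of 2 groups, and that of Sod2 when probe sets were averaged (-1, adjusted p = 0.211).

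Markers of fibroblasts, a cell type a culture could hold, were higher as a list (23 measured, median 1.02, adjusted p = 0.0191, but adjusted p = 0.563 with an estimated correlation). A single member rose, Ccn2, a matricellular growth factor gene (19.7-fold), and another fell, Fn1, the fibronectin gene (-2.26 ± 0.56). Of the fibrillar collagen genes abundant in fibroblasts, none passed the test: Col1a2 read 16.5 and 25.6 in the homozygous lines against 7.84 in wild type, Col1a1 4.43 and 10.9 against 5.39, and Col3a1 0.400 and 4.44 against 6.52. A second Col1a1 probe set read 2.97 and 12.9 against 0.468. Dcn and Ccn1 stood higher than these collagen genes on the probe sets used, also without passing. Ccn1 read 23.5 and 28.9 against 6.33 (2.68), and Dcn 6.35 and 2.82 against 0.296 (3.10, but 0.20 on another probe set). Of the 23 members, 15 stood above the median gene and 8 below. The trophoblast list was higher (19 measured, median 0.54, adjusted p = 0.0481, but adjusted p = 0.563 with an estimated correlation) with Krt8 and Krt18 as its risen members. Its call also ended after quantile normalization, after either centring, with a sixteenth (1/16) of the pseudocount and without the filter on dim genes. Lists of CDK inhibitors and p53 targets (24 measured, median 0.70, adjusted p = 0.0385) and of the integrated stress and unfolded protein responses (24 measured, median 0.40, adjusted p = 0.0369) were higher without any member passing, and both calls ended with an estimated correlation (adjusted p = 0.563), without the filter on dim genes and with probe sets averaged. That of the first ended in the fit of 2 groups too. Genes of primitive streak and mesoderm (median -0.11, adjusted p = 0.86), neuroectoderm (0.16, adjusted p = 0.914), the response to LIF and STAT3 (-0.04, adjusted p = 0.435) and the germline and 2-cell state (-0.01, adjusted p = 0.86) were not called. Single members fell all the same. Stmn2, a neuronal gene, fell by 1.80 on the log2 scale. Of the LIF and STAT3 list, Pim3 fell by 1.76 and Spry4 at least 3.77-fold, the last without a call when probe sets were averaged (adjusted p = 0.314). Imprinted genes (median 0.00, adjusted p = 0.667), actin and adhesion genes (0.40, adjusted p = 0.283) and reference genes (0.07, adjusted p = 0.3) were not called either; Meg3, an imprinted noncoding RNA, fell 4.73-fold, and Epcam, an epithelial adhesion gene, fell 2.57-fold. Both calls ended when probe sets were averaged (Meg3 -0.84, adjusted p = 0.31; Epcam -0.67, adjusted p = 0.2).

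**Figure D2:**
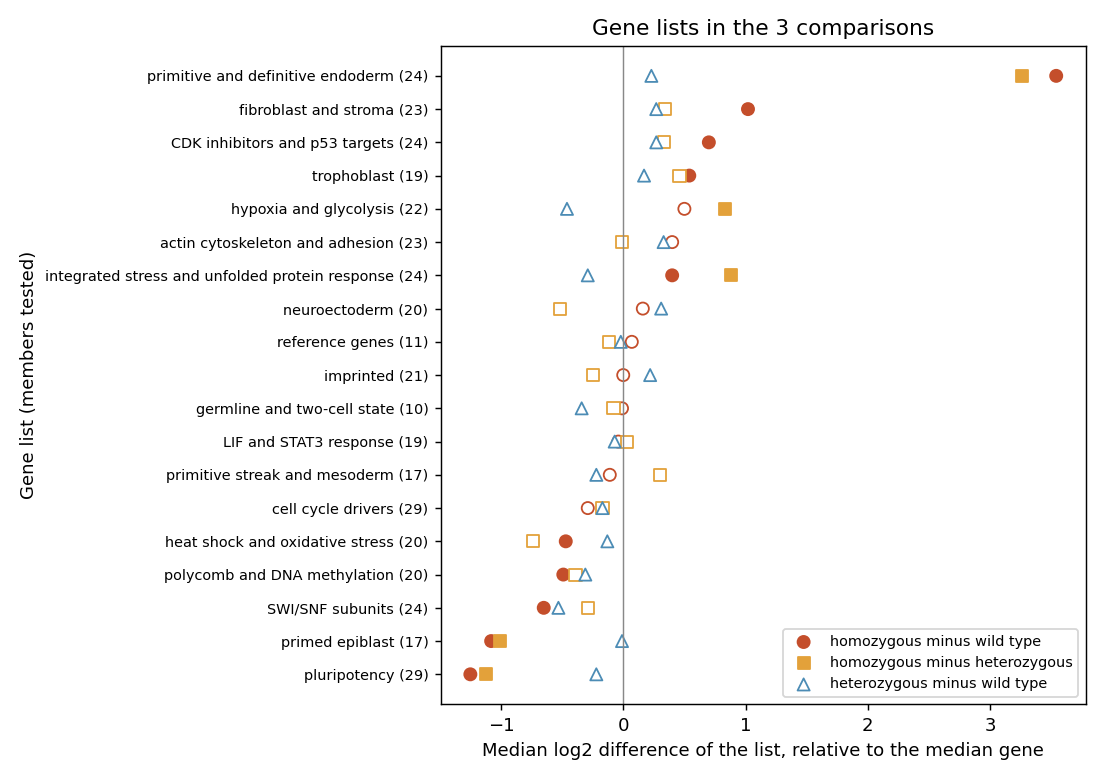
Median log2 difference of each gene list relative to the median gene (horizontal axis) in the 3 comparisons, with the number of members tested in brackets; filled symbols have a camera adjusted p under 0.05 with the preset correlation, open symbols do not. The endoderm list lies at 3.54 against wild type and 3.26 against heterozygous, and at 0.23 for heterozygous minus wild type. No filled symbol keeps its call with an estimated correlation, a setting that rests on 1 residual degree of freedom.

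Over all 13729 genes, limma called 139 in homozygous against wild type, 55 higher and 84 lower, and 1630 had an unadjusted p under 0.05. The split turned with the scaling: quantile normalization called 33 genes, 32 higher and 1 lower (Arid1a), median centring 53, 45 higher and 8 lower, and centring on the tested genes, chosen after the data were seen, 50, 45 higher and 5 lower. Of the 55 higher calls, 30 were also made after quantile normalization, among them each of the 12 named rises, whereas Arid1a alone of the 84 lower calls was (adjusted p = 0.0342, range over its alternatives 1.2e-07 to 0.545). In all, 23 rises, those 12 among them, and 32 falls besides Arid1a were named. A sixteenth (1/16) of the pseudocount ended the calls of 4 of the 23 rises, Gata4, Sox17, Krt8 and Ccnd2. It also ended those of 15 of the 32 falls: Tet1, Bcam, Parp1, Myrf, Tigd5, Ccnd1, Cbx7, Epcam, Jarid2, Mcm2, Mycn, Nr0b1, Pcna, Sod2 and Spry4. After median centring 6 of the 32 falls held, Trh, Slc7a3, Fgf4, Phc1, Meg3 and Utf1. A fit in which the variance does not follow intensity called 0 genes, with 1232 at an unadjusted p under 0.05.

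Homozygous cells were compared with heterozygous cells as well, which asks what loss of the remaining copy changes; these arrays had like median signals. Lama1 rose at least 63.7-fold (adjusted p = 1.57e-15), P4ha1 at least 29.3-fold and Pth1r at least 13.1-fold. Serpinh1, the gene of the collagen chaperone HSP47, rose at least 51.5-fold on its brighter probe set, with 627 and 194 against 2.16. The other read 65.2 and 60.8 against 11.8, above background in heterozygous. Of the 24 endoderm genes, 11 rose and 0 fell (median 3.26, camera adjusted p = 2.17e-18, but adjusted p = 0.686 with an estimated correlation). Falls were few: Trh (at least 15.7-fold), Meg3 (-3.29 ± 0.55, adjusted p = 0.000113, but -1.92, adjusted p = 0.279, with probe sets averaged), Arid1a and Bcam led, and Fgf4, Tdgf1, Fn1 and Mtm1 were the remaining ones, of which Mtm1 was named after its value was seen. The call of Fgf4 ended when probe sets were averaged (-0.91, adjusted p = 0.832). Those of Bcam, Fgf4, Tdgf1 and Fn1 also ended with a sixteenth (1/16) of the pseudocount, after quantile normalization and after either centring. The pluripotency list had a median of -1.12 with 2 of 29 members falling (adjusted p = 0.000185, but adjusted p = 0.686 with an estimated correlation), and the primed epiblast list -1.01 with the same p-values. The hypoxia and glycolysis list (median 0.83, adjusted p = 0.00247) and the stress response list (median 0.88, adjusted p = 0.00209) were higher in this comparison, again lost with an estimated correlation (adjusted p = 0.686). In all, 104 genes were called, 96 higher and 8 lower, with 943 at an unadjusted p under 0.05. In the simulations of this comparison, 99% of rises by 4 but 27.4% of falls by 4 were recovered. The split of the calls thus does not give the true balance of rises and falls. Quantile normalization gave 41 higher and 4 lower, and the fit without an intensity trend 0, with 1057 at an unadjusted p under 0.05.

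Heterozygous cells were set against wild type with 1 array on each side, the weakest comparison, since its spread came wholly from the homozygous lines. Necab2, which encodes a neuronal calcium-binding protein, fell from a signal of 32.3 to 0.740, below background (adjusted p = 0.0336). Serpinh1, named after its value was seen, was called lower on its brighter probe set (2.16, below background, against 33.7, adjusted p = 0.0245). Its other probe set went the opposite way, 11.8 against 3.74 in wild type, and the call ended when probe sets were averaged (-0.38 ± 0.61, adjusted p = 0.589). These were the 2 genes called by limma as deposited, with 1039 at an unadjusted p under 0.05; quantile normalization called 0, with 405 at that level. The other genes with the largest differences each way, none past the test, were lower in heterozygous for Sncb (0.464 against 23.5), Cenpm (0.582 against 23.5), Flcn (0.632 against 24.3), Crebzf and Pramel12, and were higher for Ccin (10.0 against 0.436), Tbc1d9 (8.23 against 0.260), Acot12, Vwa8, Ggh and Pelo. No gene list was called: the endoderm list stood at 0.23 (adjusted p = 0.788), pluripotency at -0.22 (adjusted p = 0.608) and SWI/SNF subunits at -0.53 (adjusted p = 0.608).

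Against wild type and heterozygous together, the homozygous lines had 90 called genes, 61 higher and 29 lower. Col4a2 (adjusted p = 1.95e-31) and Lama1 were among the higher and Trh and Arid1a (adjusted p = 2.25e-06) among the lower. Quantile normalization gave 201 calls, 148 higher and 53 lower, median centring 137, 107 higher and 30 lower, and the fit without an intensity trend 8. Every array mattered to the count, which was 14 without ko1, 32 without ko2, 160 without wild type and 231 without heterozygous.

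By size alone, 3765 genes differed 2-fold or more from wild type in both homozygous lines, 873 higher and 2892 lower. Relative to the median gene these were 1682 higher and 1021 lower. Unchanged groups simulated against the same wild type array gave 3101 such genes on average. Centred on the tested genes the count was 2722, against 2290 simulated. Most of either count thus needs no difference between genotypes. Between ko1 and ko2 themselves 5275 genes differed 2-fold or more, and between heterozygous and wild type 6223 (relative to the median gene 5143 and 4792), so that a 2-fold difference was within the spread between replicate lines. Across genes, which are not independent replicates, the log2 values of ko1 and ko2 correlated at r = 0.652 and those of wild type and heterozygous at r = 0.666. Of the 3765 genes, 56.5% (Wilson 95% interval 54.9% to 58.1%, counting error only) had a heterozygous value nearer to the homozygous mean than to wild type. In the simulated unchanged groups the share was 68.9% on average, between 67% and 71.4% in 100 simulations, so the observed share lay below each of the 100. Centred on the tested genes it was 48.1% against 61.9%, between 59.2% and 65.2%, again below each. No chromosome was called in any comparison: in homozygous against wild type the medians ran from -0.22 (Y, 7 genes) to 0.08 (chromosome 12), with camera adjusted p of 0.98 or more and 0 at an unadjusted p under 0.05.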

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

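The tests of explanations in this part were all chosen after the results were seen. Control probe sets outside the gene comparisons differed between arrays: the actin 3' to 5' ratio was 5.01 in ko1, 2.61 in ko2 and 2.86 in heterozygous against 1.3 in wild type, and the Gapdh ratio was 2.57 in ko1, 1.21 in ko2 and 1.27 in heterozygous against 1.1 in wild type. A probe set without a single gene name read 78.9 in ko1 and 50.4 in ko2 against 0.481 in wild type and 8.79 in heterozygous, the only one of 10092 such probe sets, 51 controls left out, at 8-fold or more above wild type in both lines and above heterozygous.

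The first pattern is the rise of the endoderm list, with a median of 3.54 against wild type and 3.26 against heterozygous. A uniformly lower signal of the homozygous arrays is left untested, since these medians already leave out the level of each array. 3' bias would leave no difference between ko2 and heterozygous, with actin ratios of 2.61 and 2.86, but ko2 minus heterozygous was 2.84. Both medians against heterozygous, 3.26 and 2.84, lay above each of 10000 random lists. For ko1, at 3.69 with an actin ratio of 5.01, no array of like ratio exists, so 3' bias and a true rise cannot be told apart. Fibroblast or feeder cells as the whole cause would raise the fibroblast list by about as much, but its median was 1.02 (SD of the members 1.61) and Fn1 fell from 144 to 10.9 and 27.3; a smaller share of such cells is not excluded, as that list was itself called higher (adjusted p = 0.0191). Whether a share of differentiated cells arose in the cultures, or every cell changed, cannot be told apart. The pluripotency list had a median of -1.25, and its members had an SD of 1.03 against a mean error of 0.67 (chi-squared p = 2.87e-06). That p-value takes the genes as independent and their errors as known, although the errors rest on 1 residual degree of freedom and the trend. A wider spread would come from a share of cells that retain some of these transcripts as well as from a change in every cell. Bulk RNA holds no cell-level value. Loss of BAF250 stays open as the biological hypothesis and untested, since genotype, line and culture are confounded with 1 wild type array.

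The second pattern is the fall of the pluripotency list. Against the heterozygous array its median was -1.12, and ko2 minus heterozygous, of like actin ratio, was -1.03. Both lay below each of 10000 random lists of like expression. The ko2 value argues against 3' bias as the whole cause in ko2. A uniformly lower signal is left untested here too, since these medians already leave out the level of each array. In ko1 (-1.32) 3' bias and a true fall cannot be told apart, for want of an array of like ratio. A share of differentiated cells and a change in every cell remain open here too.

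The third pattern is the excess of lower calls against wild type, 84 against 55. Whether deposited arrays without a common scale or a true excess of falls made it cannot be told apart. The excess turned to 32 higher and 1 lower after quantile normalization and 45 and 8 after median centring. Such rescaling would take out a true excess too. Simulated data sets with unequal array levels and 200 changed genes had 34.7 unchanged genes called lower and 2.3 called higher on average. Against the heterozygous array, of like median signal, there were 8 lower and 96 higher calls. There 27.4% of simulated falls by 4 and 99% of rises by 4 were recovered, and 48.8% and 95.4% against wild type. A single wild type array cannot separate its scale from a true excess of falls against it.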

How the results depend on the processing

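Centring on the tested genes and the list test in the fit of 2 groups were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because wild type and heterozygous have 1 array each. For homozygous against wild type, the 139 calls became 55 with a sixteenth (1/16) of the pseudocount, 33 after quantile normalization, 53 after median centring, 50 when centred on the tested genes, 44 with no filter, 0 without the intensity trend (1232 at an unadjusted p under 0.05) and 231 with homozygous and wild type arrays only. For homozygous against heterozygous, 104 became 45 after quantile normalization, 67 after median centring, 48 when centred on the tested genes, 55 with no filter, 0 without the trend (1057 unadjusted) and 160 with these arrays only. For heterozygous against wild type, 2 became 22 with probe sets averaged and 0 with a lower pseudocount, quantile normalization, either centring, no filter, a 60th percentile filter, every probe set or no trend (1008 unadjusted). Against wild type and heterozygous together, 90 became 201 after quantile normalization, 137 and 168 after the centrings and 8 without the trend, and 14 to 231 without single arrays (14 without ko1, 32 without ko2, 160 without wild type, 231 without heterozygous). The share of heterozygous values nearer to homozygous, 56.5%, was 45.8% after quantile normalization, 48.6% and 48.1% after the centrings, 58.6% with probe sets averaged, and 50.7% (without ko2) to 55.1% (without ko1). With 1 homozygous line the 2-fold rule took 6601 to 6843 genes instead of 3765, which follows from asking 1 line instead of both. The 10 called lists became 6 with probe sets averaged and 0 with an estimated correlation, a setting that rests on 1 residual degree of freedom. Arid1a kept -3.52 without the trend but not its call (adjusted p = 0.545; 1.2e-07 to 0.0342 elsewhere). The total degrees of freedom fell from 47.83 to 9.262 after quantile normalization, 16.16 and 12.45 after the centrings and 6.45 without the trend, and rose to 144.5 with the 40th percentile pseudocount and 13730 with probe sets averaged, where the variance came wholly from the trend; the cause of the shifts was not tested. Chromosomes stayed at 0 calls under each alternative run.

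Of the 23 named genes called higher against wild type, the 12 named by rule among them, 20 kept their call after quantile normalization. The number was 19 with a sixteenth (1/16) of the pseudocount, 21 after either centring or with probe sets averaged and 0 without the trend. Of the 32 called lower besides Arid1a, 0 kept their call after quantile normalization, 17 with that pseudocount, 6 and 4 after the centrings, 23 with probe sets averaged and 0 without the trend. No called gene named here and no called list reversed under an alternative run. Signal over background limits the dim side: 34% to 59.9% of tested genes were at or below background on an array.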

Other observations

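Serpinh1 was higher in the homozygous lines than in wild type on both of its probe sets, set out here after its values were seen: 627 and 194 against 33.7 (log2 difference 4.09 ± 0.57, adjusted p = 0.000262) and 65.2 and 60.8 against 3.74, below background. In heterozygous the probe sets read 2.16 and 11.8.

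Y-linked and X-inactivation genes were near background and too few to test as a list. Of its 4 tested members, Xist read 6.13, 7.40, 13 and 4.44 and Eif2s3y 7.39, 2.26, 5.33 and 3.45 in ko1, ko2, wild type and heterozygous. Actb, a common reference gene, read 573 in ko1, 1510 in ko2, 3510 in wild type and 1310 in heterozygous on the probe set used. The difference depended on the probe set. In the same order, the control probe set at the 3' end read 1180, 1110, 2200 and 1170, and the one at the 5' end 235, 423, 1700 and 410.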
